A study of Gallus gallus with 24 samples.

How the data were processed

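Poly(A) RNA from the left and the right gonads of female Leghorn chicken embryos was sequenced at embryonic day (E) 5, 6.5, 8 and 9.5, with 3 libraries per side and stage and 24 in all. RNA was extracted with a Zymo Direct-zol kit and made into libraries with an NEB kit, per the labels. The labels do not say whether the libraries of a group are separate embryos, pools of embryos or repeated preparations, so each p-value measures the spread between these samples, which may be technical. Between libraries of a group chi-square per degree of freedom ran from 8.04 to 60.9 over 24 pairs, more than counting noise alone gives. This argues against the same library sequenced again, but does not tell embryos, pools and separate preparations apart.

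The deposited table holds read counts per gene for all 24 libraries, as whole numbers that the authors had not normalised. Per the labels, the authors trimmed reads with Trim Galore 0.6.7, aligned them with STAR 2.7.10a to the build GRCg6a and counted them with HTSeq 2.0.0. The strand setting and the counting mode are not given in the sources used here. The table has 24154 genes, of which 15723 carry a symbol, 8407 a LOC number and 24 a mitochondrial RNA locus tag, and 1617 have no count in any library. Totals per library ran from 15078282 to 19970859 counts, a ratio of 1.32. Gene coordinates were not used here.

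Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 16694 genes, 13489 with a symbol and 3188 with a LOC number. Libraries were scaled with TMM factors, and 1 quasi-likelihood model with a mean for each of the 8 groups was fitted to all 24 libraries. The biological coefficient of variation was 0.212. Contrasts compared left with right at each of the 4 stages, E9.5 with E5 in each gonad, and the left-right difference at E9.5 with that at E5. An F test asked whether the left-right difference varied over the 4 stages. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and each standard error (SE) is the log2 fold change divided by the square root of F. Levels are CPM from edgeR on TMM-scaled totals, as mean and SD of 3 libraries. Positive log2 values mean more transcript in the left gonad or at E9.5. The test was run on simulated data with known changes made from the same libraries. At E5 it called 69% of genes with a change of 2-fold and 89% of those with a change of 4-fold, and at E9.5 66% and 94%. For E9.5 against E5 in the left gonad it called 61% and 88%, for the difference of differences 46% and 85%, and for the F test over stages 42% and 81%. Genes left unchanged made up 7.60% of the calls at E5 (13 of 171), above the threshold of 5%, and 4.19%, 1.97%, 5.07% and 2.38% in the other tests in this order. Simulated counts were drawn independently for each gene and library, with changes only in genes of at least 1 CPM. They lack the variation that genes share between the real libraries, so these rates may not hold for the real data.

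The question, the groups, the tests, 27 gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. Lists were tested with camera (preset correlation between genes of 0.01, voom weights, limma), adjusted over the lists of a comparison with at least 3 tested members, and again with a correlation estimated from the data and with fry. The lists reported were embryonic left-right axis, ovarian somatic and pre-granulosa, testis and Sertoli, germ cell, meiosis, steroid hormone synthesis, retinoic acid, surface epithelium and mesothelium, stroma and extracellular matrix, cell cycle, apoptosis, WNT signalling, BMP, activin and TGF-beta signalling, hedgehog and PDGF signalling, red blood cell, mesonephros, adrenal cortex and chromaffin, neural and glial, macrophage and leukocyte, endothelium, Müllerian duct, muscle, immediate early and heat shock, hypoxia and glycolysis, mitochondrially encoded genes and the W chromosome. No name of the mitochondrially encoded list matched the table (0 of 29), so 26 lists were tested. Some genes stand in more than 1 list, as EMX2, AMHR2, PAX2 and PDGFRA do. Lists of liver, interferon-stimulated and heterophil genes were written after the data were seen.

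The named genes of each comparison are the 10 largest changes each way among genes with a symbol, an adjusted p under 0.05, a mean of at least 2 CPM and no overlap between the libraries of the compared groups (for the difference of differences, without the overlap condition). To these come a panel of 20 genes given whether or not they passed (among them CYP19A1, FOXL2, ESR1, NR5A1, ALDH1A2, CYP26B1, BMP7, CCND1, WNT4, RSPO1, DMRT1, SOX9, AMH, HSD17B1, CYP17A1, STRA8, DDX4, DAZL and SYCP3) and, within each list, up to 4 passing genes with the largest change. 1 list and some genes that meet these rules are not reported here. Genes named outside this rule are given as chosen after their values were seen.

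The other settings were RLE size factors, a filter of at least 1 CPM in at least 3 libraries, no filter beyond a total above 0, libraries thinned to the shallowest, DESeq2 1.42.0, a fit of the compared libraries alone, a block for libraries that share a replicate number, and each library left out in turn. Where a library is left out, its group keeps 2 libraries and the spread is pooled over the groups. After the data were seen, a mesonephros score and an adrenal and chromaffin score as covariates were added, and a run without 2 libraries that hold liver transcripts. Left and right libraries with the same number resembled each other at E5 (correlation across genes, after removing the group means, from 0.35 to 0.52) and at E9.5 (0.28 to 0.42). At E6.5 (-0.16 to 0.53) and E8 (-0.02 to 0.13) they did not all do so, so blocked values stand beside the results only at E5 and E9.5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library or column was left out.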

Results

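The data are read counts per gene from 24 libraries of female chicken embryonic gonads, left and right, at 4 stages. In female birds the left gonad becomes the ovary and the right one regresses, and the stages cover the days over which the gonads take on ovarian character. Each side and stage has 3 libraries. Totals ran from 15078282 counts (E5 right, replicate 3) to 19970859 (E9.5 right, replicate 2). The first principal component of the 1000 most variable genes held 48.1% of the variance and the second 27.1%. The first ran from -65.2 (E5 right 3) to 64.3 (E9.5 right 2), where the mesonephros list had a mean log2 CPM of 2.31 and 6.64. Other libraries far out on it went the same way. E6.5 left 2 lay at -52.1 with 1.53 for that list, E6.5 right 3 at 44.8 with 6.61, and E8 right 1 at 55.9 with 6.44. The order was not strict, since E5 right 1 and E8 right 3, at 4.67 and 4.66 for that list, lay at -26.1 and 24.4. The relation over all libraries was not tested. The comparisons ask how the left gonad differs from the right at each stage, whether that difference changes between stages, and how each gonad changes from E5 to E9.5.

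At E5 MSTN, which encodes the growth inhibitor myostatin, was 129-fold higher in the left gonad, at 20 ± 5.81 CPM (SD, n = 3) against 0.149 ± 0.209 in the right (log2 7.01 ± 0.56 SE, adjusted p = 3.7e-07). The right value was near the bottom of the range, so the size of this fold is uncertain. GRIA1, a glutamate receptor subunit, stood at 26.5 ± 5.92 against 2.67 ± 0.625 CPM, and PALMD at 60.8 ± 11.6 against 3.61 ± 1.14 CPM (log2 3.30 ± 0.28 and 4.07 ± 0.33). On the right, CPNE8 (log2 -1.89 ± 0.13), C4H4ORF32 (-1.28 ± 0.14) and the complement gene C7 (-1.26 ± 0.21, adjusted p = 0.0018) were higher. FOXL2 and CYP19A1 (aromatase), both of the ovarian programme, were near the bottom of the range on either side, at 0.810 against 0.770 and 0.959 against 0.547 CPM, and did not pass.

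In all, 490 genes differed at E5, 320 higher and 170 lower in the left gonad, and 235 of them by at least 2-fold (200 and 35). The values of the left and right libraries did not overlap for 18.5% of genes tested, against 10% by chance. The count was 236 without left replicate 2, 252 without left replicate 3, 291 without right replicate 1, 238 without right replicate 3, and 222 in a fit of the 6 compared libraries alone. With the replicate block it was 814, and AMH passed there (log2 0.85, adjusted p = 0.0081), while ADM (-0.52, 0.10) and TLR4 (-0.71, 0.085) lost their calls.

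Germ cell genes were the clearest group at E5. Of 27 tested, 16 were higher in the left gonad and none lower (20 adjusted over the list alone), with a list median of 1.25 (camera adjusted p = 8.4e-26, and adjusted p = 0.029 with an estimated correlation). Examples are DMRTB1 (log2 1.72 ± 0.26), the pluripotency factor NANOG (1.71 ± 0.30), the RNA helicase DDX4 (1.38 ± 0.23, 42.7 ± 9.28 against 16.4 ± 6.11 CPM) and DAZL (1.45 ± 0.25, 145 ± 19.4 against 53.2 ± 17.2 CPM). Some genes of the panel passed at E5 but lost their calls when single libraries were left out. NR5A1 (log2 1.08) had adjusted p = 0.085, 0.11, 0.14 and 0.098 without left 2, left 3, right 1 and right 2. ESR1 (1.23) had 0.31, 0.15 and 0.10 without left 2, right 1 and right 3. ALDH1A2, a retinoic acid synthesis enzyme (-0.59), had 0.12, 0.21, 0.20 and 0.17 without left 1, left 3, right 2 and right 3. BMP7 (0.46) had 0.052, 0.11, 0.24, 0.23, 0.11 and 0.051 without left 1, 2 and 3 and right 1, 2 and 3.

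Macrophage and leukocyte genes were lower in the left gonad at E5 (0 higher and 5 lower of 16, 1 and 10 adjusted over the list alone). For macrophage genes the median was -0.61, with adjusted p = 5.8e-08, and adjusted p = 0.029 with an estimated correlation. An example is CTSS (log2 -0.70, adjusted p = 0.066 without left 2). Endothelial genes were lower as a list (0 higher and ERG lower of 17, 1 and 9 adjusted over the list alone). For endothelial genes camera gave adjusted p = 1.1e-04, and adjusted p = 0.17 with an estimated correlation. ERG had adjusted p = 0.059 without left 2 and 0.054 without right 3. Stroma genes were lower as a list (1 higher and 3 lower of 24, 1 and 5 adjusted over the list alone). For stroma genes camera gave adjusted p = 6.5e-04, and adjusted p = 0.28 with an estimated correlation. Among them were OGN (-1.30 ± 0.25) and the transcription factor TCF21 (-0.92 ± 0.18). The stroma call was lost without right replicate 3 (adjusted p = 0.14) and with fry (0.11). Surface epithelium genes were higher (2 higher and none lower of 19, 3 and 1 adjusted over the list alone). For surface epithelium genes camera gave adjusted p = 0.0026, and adjusted p = 0.16 with an estimated correlation. The genes were EMX2 (log2 1.14 ± 0.13) and KRT7 (0.76, adjusted p = 0.055 without left 3). The cell cycle list moved up with no single gene past the threshold in edgeR (0 of 28, 0 adjusted over the list alone). For cell cycle genes the median was 0.18, with adjusted p = 1.5e-05, and adjusted p = 0.17 with an estimated correlation. With the replicate block the embryonic left-right axis (adjusted p = 0.046), adrenal and chromaffin (down, 0.038) and hypoxia (0.017) lists passed too. Without the block they had adjusted p = 0.16, 0.75 and 0.20 with an estimated correlation. Outside the passing lists, FAS, a death receptor (log2 2.49 ± 0.28), WNT11 (1.37 ± 0.22), BMP3 (1.90 ± 0.30) and TGFBI (1.06 ± 0.19) were higher in the left gonad.

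At E6.5 GRIA1 stood at 64.4 ± 12.9 CPM in the left and 3.08 ± 0.619 in the right gonad (log2 4.39 ± 0.29, adjusted p = 3.0e-08, n = 3 per side), and MSTN 18.4 ± 3.14 against 0.597 ± 0.288 CPM (4.93 ± 0.47). PALMD (log2 3.12 ± 0.33), RPH3A (3.08 ± 0.25) and CAMP, a cathelicidin of blood granulocytes (3.96 ± 0.74, 4.39 ± 1.20 against 0.275 ± 0.0755 CPM), were higher on the left as well. CPNE8 (-1.20 ± 0.12), ADAMTS17 (-1.19 ± 0.18) and the RNA-editing family member ADARB2 (-1.92 ± 0.30) were higher on the right. CYP19A1 stood at 260 ± 142 CPM on the left and 297 ± 56.6 on the right, and FOXL2 at 24.04 ± 8.74 and 25.7 ± 6.94 CPM, with no difference past the threshold (adjusted p = 0.86 and 0.92).

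At this stage 541 genes differed, 445 higher and 96 lower in the left gonad, 290 of them by at least 2-fold (263 and 27). The libraries of the sides did not overlap for 15.6% of genes, against 10% by chance. The count fell to 203 without left replicate 2, 259 without right replicate 1, 198 without right replicate 3, 279 with the mesonephros score as a covariate and 77 in a fit of the 6 compared libraries alone. In that fit 30 of 50 named genes called at E6.5 lost their call, among them DDX4 and DAZL, and with the mesonephros covariate 16 of 50 did. When single libraries were left out, 23 of the 50 lost their call at least once.

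Germ cell genes were again higher in the left gonad at E6.5, 21 of 27 with none lower (23 adjusted over the list alone). For germ cell genes the median was 1.24, with adjusted p = 2.7e-29, and adjusted p = 0.054 with an estimated correlation. DAZL stood at 157 ± 31.9 against 58.0 ± 22.2 CPM (log2 1.43 ± 0.25), DDX4 at 54.8 ± 10.1 against 21.0 ± 5.76 CPM (1.38 ± 0.23), and RNF17 and DMRTB1 had log2 values of 1.46 ± 0.29 and 1.42 ± 0.25. All lists that passed at E6.5, germ cell genes among them, lost their calls with an estimated correlation. Mesonephros genes, which mark the embryonic kidney beside the gonad, had a median of -1.67 with no gene past the threshold in edgeR (0 of 18, 0 adjusted over the list alone). For mesonephros genes camera gave adjusted p = 2.4e-04, and adjusted p = 0.37 with an estimated correlation. The mesonephros marker CUBN ranged from 8.36 to 224 CPM in the left and from 93.8 to 814 CPM in the right libraries. Adrenal and chromaffin genes were higher as a list (SCG3 higher and none lower of 13, 5 adjusted over the list alone; adjusted p = 0.023, and adjusted p = 0.59 with an estimated correlation), and neural and glial genes too (2 higher of 13, 7 and 1 lower adjusted over the list alone; adjusted p = 0.0060, and adjusted p = 0.48 with an estimated correlation), with SCG3 at log2 1.75 ± 0.29 and the neuronal gene ELAVL4 at 1.17 ± 0.19. In left replicate 3 the chromaffin granule gene CHGA stood at 247 CPM against 8.41 to 52.2 in the other 5 libraries. Without it both lists lost their calls, with adjusted p = 0.40 and 0.30, and without right replicate 1 the first had 0.10. Without the 2 libraries with liver transcripts the lists had 0.37 and 0.30.

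Endothelial genes were lower as a list at E6.5 (none lower by itself and KDR, a VEGF receptor, higher at log2 0.81 ± 0.12, of 17; 1 higher and 4 lower adjusted over the list alone). Across the endothelial list the median was -0.36, with adjusted p = 5.0e-04, and adjusted p = 0.37 with an estimated correlation. Stroma genes were lower (1 higher and 2 lower of 24, 1 and 6 adjusted over the list alone). The stroma list had adjusted p = 3.8e-04, and adjusted p = 0.37 with an estimated correlation. COL12A1 was higher (0.69 ± 0.13). Hypoxia and glycolysis genes were higher (2 of 23, 6 and 2 lower adjusted over the list alone). For hypoxia genes the median was 0.17, with adjusted p = 0.013, and adjusted p = 0.28 with an estimated correlation. Without left replicate 1 these 3 lists had adjusted p = 0.072, 0.095 and 0.087. Macrophage and leukocyte genes were lower (0 of 16, 3 adjusted over the list alone). The macrophage list had adjusted p = 0.012, and adjusted p = 0.37 with an estimated correlation. The macrophage list had adjusted p = 0.063 without left replicate 2. With fry the stroma (adjusted p = 0.10), mesonephros (0.17), adrenal and chromaffin (0.33), neural (0.20), macrophage (0.091) and endothelial (0.091) lists did not pass. EMX2 (log2 0.85 ± 0.13), KRT7 (0.88 ± 0.15), WNT11 (1.58 ± 0.22), FAS (1.52 ± 0.28) and SRD5A3, a steroid reductase family member (1.19 ± 0.16), were higher on the left.

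At E8 NTN1, the guidance molecule netrin 1, was 34.2-fold higher in the left gonad, at 92.8 ± 10.2 against 2.73 ± 1.38 CPM (log2 5.10 ± 0.54, adjusted p = 5.8e-06, n = 3 per side). The dopamine receptor gene DRD4 stood at 26.4 ± 8.86 against 1.29 ± 0.825 CPM (4.36 ± 0.51) and SHISA6 at 14.7 ± 2.97 against 0.820 ± 0.344 CPM (4.15 ± 0.34). CYP19A1 (2053 ± 364 and 2012 ± 274 CPM, adjusted p = 0.97) and FOXL2 (53.2 ± 6.39 and 81.0 ± 11.3 CPM, adjusted p = 0.14) did not pass. Of the ovarian somatic list, 1 gene was higher and 4 were lower in the left gonad (2 and 4 adjusted over the list alone, of 16): RSPO1, a WNT activator (log2 -1.74 ± 0.36), NR0B1 (-1.16 ± 0.14) and the activin antagonist FST (-1.10 ± 0.18) were lower, AMHR2 was lower at -0.49, and IRX5 was higher (1.51 ± 0.31). AMHR2 had adjusted p = 0.24, 0.065, 0.065, 0.061, 0.14 and 0.13 without left 1, 2 and 3 and right 1, 2 and 3, and the list did not pass (adjusted p = 0.36). With fry the ovarian somatic list passed, down (adjusted p = 0.013).

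Among the 10 genes with the largest change toward the right at E8 were HRG, FGA, C8A, SULT, SERPIND1, SERPINC1, APOA5, APOA2 and FETUB, most of them genes of plasma proteins made by the liver. In right replicate 3 albumin (ALB) stood at 1008 CPM and a liver gene score at 6.55. Without that library none of them passed, with adjusted p from 0.080 (APOA5) to 0.71 (FGA), and log2 values from -3.21 (APOA2) to -0.90 (FGA), against -5.64 and -7.11 with all libraries. APOA2 also lost its call without left 1 (0.066), left 2 (0.060) and left 3 (0.051), FGA without left 1 (0.057) and left 2 (0.051), and HRG without left 1 (0.054). E6.5 left replicate 3 had 170 CPM of ALB and a score of 3.29, and the other 22 libraries at most 10.1 CPM and scores from -0.68 to 2.31. In total 2379 genes differed at E8, 1259 higher and 1120 lower, 886 by at least 2-fold (527 and 359), with 39.3% of genes without overlap against 10% by chance. The count was 1349, 1481 and 1554 without left replicates 1, 2 and 3, 1433 and 1362 without right replicates 1 and 2, 2097 without the 2 libraries with liver transcripts, and 1484 with the adrenal and chromaffin score as a covariate. In a fit of the 6 compared libraries alone 1618 genes were higher and 1645 lower. With the adrenal and chromaffin covariate 44 of 96 named genes called at E8 lost their call, among them RSPO1, FST, IRX5, ALDH1A2, SPO11, SMC1B, SYCP3, STRA8, SOX8, CRABP1, SRD5A3 and SNAP25. The 44 include MC2R, MRAP, PNMT and SLC18A1, whose own values are part of the score, so the covariate does not test them. For the other genes it cannot tell carried-over tissue from a side difference. The score parted the sides at E8, at 3.46 to 5.05 in the left and 1.93 to 1.99 in the right libraries, so it takes up side differences of any origin.

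Adrenal and chromaffin genes were higher in the left libraries at E8, 10 of 13 with none lower (11 adjusted over the list alone). For adrenal and chromaffin genes the median was 3.24, with adjusted p = 2.1e-07, and adjusted p = 0.25 with an estimated correlation. MRAP (log2 6.29 ± 1.38), the corticotropin receptor gene MC2R (3.78 ± 0.73) and the adrenaline synthesis enzyme PNMT (3.70 ± 0.85) are examples, and CHGA stood at 138, 337 and 530 CPM in the left and 26.2 to 44.1 CPM in the right libraries. Neural and glial genes moved the same way (6 of 13, none lower, 7 and 1 lower adjusted over the list alone). For neural and glial genes the median was 1.39, with adjusted p = 5.0e-04, and adjusted p = 0.34 with an estimated correlation. SNAP25 stood at log2 2.89 ± 0.56. Mesonephros genes were lower (3 of 18, 5 adjusted over the list alone). Across the mesonephros list the median was -2.03, with adjusted p = 1.1e-04, and adjusted p = 0.34 with an estimated correlation. PAX2 stood at log2 -1.73 ± 0.23 and CUBN at 27.7 to 56.6 CPM in the left and 69.8 to 503 CPM in the right libraries.

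Germ cell genes stayed higher in the left gonad at E8 (18 of 27, none lower, 22 adjusted over the list alone). Across the germ cell list the median was 0.87, with adjusted p = 2.5e-13, and adjusted p = 0.17 with an estimated correlation. DDX4 stood at 84.1 ± 11.03 against 35.1 ± 4.14 CPM (log2 1.26 ± 0.23). Meiosis genes passed narrowly (4 higher and 1 lower of 15, 5 and 1 adjusted over the list alone). For meiosis genes camera gave adjusted p = 0.044, and adjusted p = 0.40 with an estimated correlation. The meiotic entry gene STRA8 (1.38 ± 0.35), SMC1B (1.35 ± 0.31) and the synaptonemal complex gene SYCP3 (0.97 ± 0.21) were higher, and the recombination gene SPO11 was lower (-2.15 ± 0.41). That list had adjusted p = 0.069, 0.16, 0.13 and 0.069 without left 1, left 2, right 1 and right 3, and 0.078 without the 2 libraries with liver transcripts. Cell cycle genes were higher (14 of 28, none lower, 23 adjusted over the list alone). Across the cell cycle list the median was 0.37, with adjusted p = 3.9e-12, and adjusted p = 0.11 with an estimated correlation. Examples are BUB1B (0.63 ± 0.11), BUB1 (0.62 ± 0.13) and TPX2 (0.59 ± 0.12).

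Retinoic acid genes were lower at E8 as a list (2 higher and 5 lower of 18, 3 and 8 adjusted over the list alone). For retinoic acid genes the median was -0.47, with adjusted p = 0.0096, and adjusted p = 0.17 with an estimated correlation. RDH10 (-1.06 ± 0.14), DHRS3 (-1.01 ± 0.13) and ALDH1A2 (-0.71 ± 0.16, 438 ± 17.2 against 715 ± 35.3 CPM), which act in making or storing retinoids, were lower, and the binding protein gene CRABP1 was higher (1.82 ± 0.35). BMP, activin and TGF-beta genes were lower (1 higher and 6 lower of 28, 1 and 7 adjusted over the list alone). For BMP genes the median was -0.34, with adjusted p = 0.0086, and adjusted p = 0.35 with an estimated correlation. The BMP targets ID3 (178 ± 10.5 against 356 ± 17.6 CPM) and SMAD6 (-0.89 ± 0.17) were lower, and BMP3 was higher (1.55 ± 0.30). Stroma genes were lower (6 of 24, none higher, 11 adjusted over the list alone). The stroma median was -0.44, with adjusted p = 1.1e-04, and adjusted p = 0.28 with an estimated correlation. Among them were TCF21 (-0.93 ± 0.18) and NR2F2 (-0.90 ± 0.17). Endothelial genes were lower (1 higher and 7 lower of 17, 1 and 14 adjusted over the list alone). The endothelial median was -0.58, with adjusted p = 7.8e-06, and adjusted p = 0.17 with an estimated correlation. PLVAP stood at log2 -0.68 ± 0.11 and KDR, the one higher, at 0.90 ± 0.12. Macrophage and leukocyte genes were lower (2 higher and 6 lower of 16, 2 and 7 adjusted over the list alone). The macrophage median was -0.69, with adjusted p = 0.0052, and adjusted p = 0.28 with an estimated correlation. An example is the protease gene CTSS (-0.89 ± 0.15).

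At E9.5 NTN1 was 27.7-fold higher in the left gonad, at 80.9 ± 2.88 against 2.86 ± 2.35 CPM (log2 4.79 ± 0.53, adjusted p = 1.0e-05, n = 3 per side). TGM4 stood at 31.6 ± 1.87 against 2.65 ± 0.106 CPM (3.57 ± 0.27) and TOM1L1 at 124 ± 25.3 against 11.5 ± 4.21 CPM (3.43 ± 0.29). The oestrogen receptor gene ESR1 stood at 50.0 ± 12.9 against 22.3 ± 4.51 CPM (1.17 ± 0.30, adjusted p = 0.017), but at adjusted p = 0.061 without left replicate 1 and 0.067 without right replicate 2. CYP19A1 (3195 ± 361 and 2857 ± 391 CPM), FOXL2 (71.9 ± 0.892 and 65.1 ± 30.5 CPM) and CYP17A1 (2386 ± 359 and 2147 ± 805 CPM) did not pass (adjusted p = 0.80, 0.78 and 0.72). PTGDS, a prostaglandin synthase, was higher on the right (-4.17 ± 0.71, adjusted p = 8.8e-04).

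The 10 largest changes toward the right at E9.5 were in KCNJ1, ATP12A, K123, GAL3ST2, PSCA, TMEM52B, SELENBP1L3, AvBD10, SIM1 and TMEM213. None passed without right replicate 2, where their adjusted p ran from 0.066 (K123) to 0.24 (TMEM52B) and their log2 values from -3.97 (GAL3ST2) to -3.08 (PSCA), against -5.68 and -5.39 with all libraries. The mesonephros list kept its call there. Some also lost their calls without left libraries. Without left 1, left 2 or left 3 the highest adjusted p among them were 0.13, 0.098 and 0.13, for AvBD10, TMEM52B and AvBD10. In right replicate 2 CUBN stood at 463 CPM, against 114 and 283 CPM in the other right and 11.8 to 69.0 CPM in the left libraries. In total 2171 genes differed at E9.5, 857 higher and 1314 lower in the left gonad, 1019 by at least 2-fold (258 and 761), with 26.2% of genes without overlap against 10% by chance. The count was 1099, 1318 and 1305 without left replicates 1, 2 and 3, 1013 without right replicate 2, 760 with the mesonephros score as a covariate and 1032 in a fit of the 6 compared libraries alone. The excess toward the right was not stable. More genes were higher than lower in the left gonad without left 1 (586 and 513), left 3 (715 and 590) and right 2 (557 and 456) and with the adrenal and chromaffin covariate (936 and 793), and the mesonephros covariate gave 379 and 381. With the mesonephros covariate 43 of 92 named genes called at E9.5 lost their call, among them ESR1, DDX4, LHX9, HSPB9, TNNC1 and SRD5A3, and the log2 of TMEM52B and AvBD10 was 0.28 and 0.18. The 43 include AMN and ASS1, whose own values are part of that score. The score parted the sides at E9.5, at 2.44 to 4.08 in the left and 4.91 to 6.64 in the right libraries. Lost calls thus cannot tell carried-over tissue from a side difference. The count was 3343 with the replicate block, where BMP7 (log2 0.35, adjusted p = 0.017), HSD17B1 (0.61, 0.024), SOX9 (1.47, 0.011) and STRA8 (0.83, 0.033) passed and ELAVL4 (0.58, 0.072) and VNN1 (-1.68, 0.084) lost their calls.

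Cell cycle genes were higher in the left gonad at E9.5 (17 of 28, none lower, 23 adjusted over the list alone). The cell cycle median was 0.42, with adjusted p = 2.2e-14, and adjusted p = 0.051 with an estimated correlation. An example is the mitotic kinase gene PLK1 (log2 0.65 ± 0.12). Germ cell genes were higher as a list (6 higher and 1 lower of 27, 10 and 2 adjusted over the list alone). The germ cell median was 0.46, with adjusted p = 0.0015, and adjusted p = 0.52 with an estimated correlation. DDX4 stood at 90.7 ± 11.8 against 51.5 ± 4.56 CPM (0.82 ± 0.22), with adjusted p = 0.069 without left 2 and 0.052 without right 3. DAZL did not pass (134 ± 23.4 against 107 ± 17.4 CPM, adjusted p = 0.42), and LIN28A, a gene of early germ cells, was lower (-1.35 ± 0.32, with adjusted p = 0.054 without left 1). SYCP3 was higher (1.04 ± 0.21, 15.9 ± 3.36 against 7.70 ± 0.715 CPM), while its list, meiosis, did not pass (2 higher and 1 lower of 15, 5 and 3 adjusted over the list alone, adjusted p = 0.087). Without left replicate 1 the meiosis list passed (camera adjusted p = 0.040).

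Mesonephros genes were lower in the left libraries at E9.5 (6 of 18, none higher, 14 adjusted over the list alone). The mesonephros median was -3.08, with adjusted p = 3.5e-05, and adjusted p = 0.40 with an estimated correlation. PAX2 stood at log2 -2.44 ± 0.24. Adrenal and chromaffin genes were higher (3 of 13, none lower, 7 adjusted over the list alone). Across the adrenal and chromaffin list the median was 1.61, with adjusted p = 0.0095, and adjusted p = 0.52 with an estimated correlation. MC2R stood at log2 3.80 ± 0.75, but the list had adjusted p = 0.20 without left replicate 3, where CHGA stood at 220 CPM against 28.4 to 87.0 in the other 5 libraries. Stroma genes were mostly lower (2 higher and 9 lower of 24, the same numbers adjusted over the list alone). For stroma genes the median was -0.39, with adjusted p = 0.0095, and adjusted p = 0.44 with an estimated correlation. Examples are COL14A1 (-1.15 ± 0.17) and TCF21 (-1.12 ± 0.18). Without right 1 the list had adjusted p = 0.055. Macrophage and leukocyte genes were lower (4 of 16, none higher, 7 adjusted over the list alone). For macrophage genes the median was -0.57, with adjusted p = 0.0015, and adjusted p = 0.28 with an estimated correlation. CD74, the invariant chain of antigen presentation, stood at log2 -0.96 ± 0.11. Retinoic acid genes were lower (1 higher and 5 lower of 18, 1 and 6 adjusted over the list alone). Across the retinoic acid list the median was -0.30, with adjusted p = 0.033, and adjusted p = 0.28 with an estimated correlation. ALDH1A3 stood at log2 -1.17 ± 0.17, DHRS3 at -0.99 ± 0.13 and CRABP2, the one higher, at 1.03 ± 0.19. That list had adjusted p = 0.070, 0.055 and 0.053 without left 1, right 1 and right 3. Immediate early and heat shock genes were higher (ATF3 at 1.56 ± 0.22 and HSPB9 at 0.81 ± 0.17, of 20, the same adjusted over the list alone). For immediate early genes the median was 0.14, with adjusted p = 0.033, and adjusted p = 0.32 with an estimated correlation. The list had adjusted p = 0.054 without left 3 and 0.085 without right 1. With fry the germ cell list had adjusted p = 0.11 and the adrenal and chromaffin list 0.13. EMX2 (1.68 ± 0.13), KRT7 (1.40 ± 0.15) and LHX9 (0.82 ± 0.18) of the surface epithelium list were higher, though the list did not pass (adjusted p = 0.087). It passed, up, with fry and without left replicate 3.

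**Figure D1:**
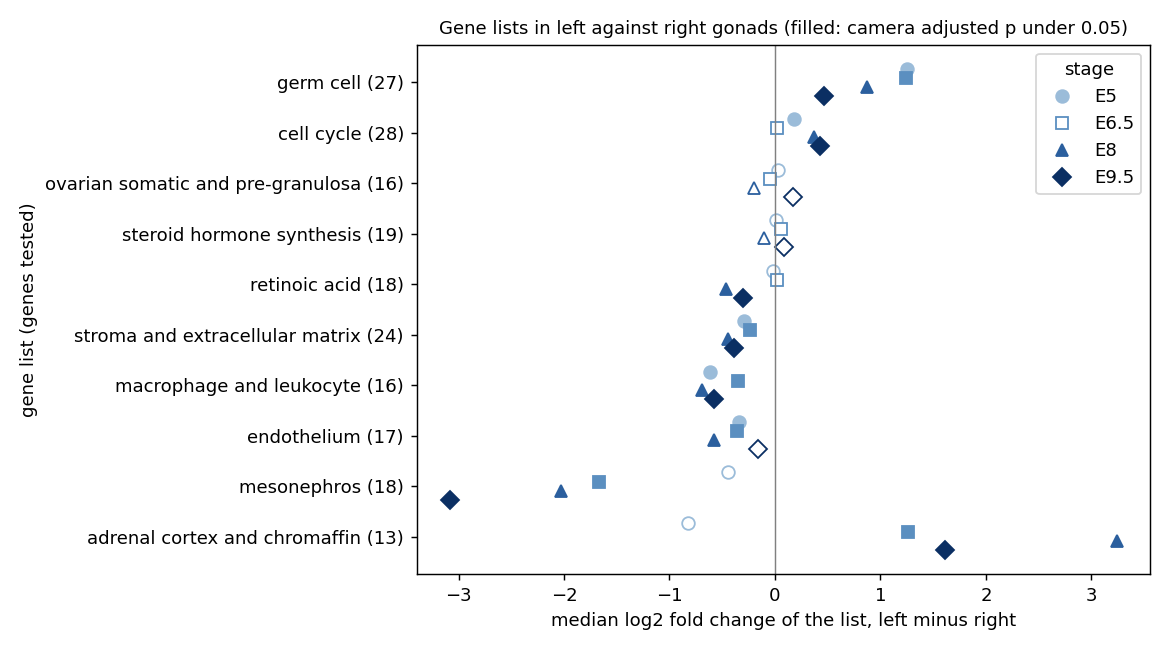
Median log2 fold change of left over right (horizontal axis) for 10 gene lists at each stage, with filled points where camera passed at an adjusted p under 0.05. The germ cell list stands at 1.25 at E5 and at 0.46 at E9.5, the mesonephros list reaches -3.08 and the adrenal and chromaffin list 3.24.

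Of the lists, 11 passed at no stage between the sides in the main setting, nor with an estimated correlation. With fry the embryonic left-right axis passed at E5 and E6.5 (up), and ovarian somatic and hedgehog genes at E8 (down). Some passed with a library left out. These were the left-right axis at E5 (left 2 or right 1) and hedgehog and muscle genes at E6.5 (left 3). At E9.5 they were hedgehog (right 1) and apoptosis genes (left 3 or right 2). Steroid synthesis genes (19 tested) had adjusted p = 0.45, 0.81, 0.96 and 0.43 at E5, E6.5, E8 and E9.5, with 2, 1, 2 and 1 genes higher and 0, 0, 0 and 1 lower (2, 1, 2 and 2 higher and 0, 0, 1 and 1 lower adjusted over the list alone), and SRD5A3 was higher at E8 (log2 0.78) and E9.5 (0.71). Ovarian somatic genes had adjusted p = 0.69, 0.57 and 0.44 at E5, E6.5 and E9.5, with 1, 0 and 2 of 16 higher and 0, 0 and 2 lower (1, 0 and 4, and 0, 0 and 3, adjusted over the list alone). Testis and Sertoli genes (14) had 0, 0, 1 and 0 higher and 0, 0, 3 and 4 lower (0, 1, 1 and 1, and 0, 0, 4 and 4, adjusted over the list alone; adjusted p = 0.44, 0.42, 0.15 and 0.70), with SOX8 higher at E8 (3.13 ± 0.51). WNT genes (29) had 2, 2, 3 and 4 higher and 1, 1, 7 and 5 lower (4, 2, 6 and 4, and 1, 2, 9 and 6, adjusted over the list alone; adjusted p = 0.65, 0.99, 0.72 and 0.87), with the WNT inhibitor DKK1 lower at E8 (-1.48 ± 0.19) and E9.5 (-1.09 ± 0.19) and WNT6 higher at E9.5 (1.71 ± 0.23). Apoptosis genes (22) had 2, 1, 1 and 1 higher and 1, 1, 2 and 1 lower (the same adjusted over the list alone; adjusted p = 0.85, 0.49, 0.96 and 0.099), with BMF lower at E8 (-1.11 ± 0.13) and E9.5 (-0.85 ± 0.13).

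Embryonic left-right axis genes (7) had 1, 2, 1 and 2 higher and 0, 0, 2 and 2 lower (1, 2, 2 and 2, and 1, 0, 3 and 3, adjusted over the list alone; adjusted p = 0.060, 0.11, 0.78 and 0.53), with FGF8 lower at E8 (log2 -2.24 ± 0.45) and E9.5 (-2.42 ± 0.48). Hedgehog and PDGF genes (16) had 1, 1, 1 and 0 higher and 1, 1, 1 and 3 lower (1, 2, 1 and 0, and 2, 3, 5 and 3, adjusted over the list alone; adjusted p = 0.63, 0.11, 0.054 and 0.12), with PDGFA higher at E5 (0.65 ± 0.11). Müllerian duct genes (8) had 1 higher at each stage, EMX2, and 0, 0, 3 and 2 lower (0, 0, 3 and 3 adjusted over the list alone; adjusted p = 0.85, 0.88, 0.58 and 0.43). Muscle genes (10) had none higher and 1, 1, 2 and 1 lower (1, 1, 3 and 2 adjusted over the list alone; adjusted p = 0.21, 0.99, 0.52 and 0.20), with TNNC1 lower at E9.5 (-2.12). Red blood cell genes (12) had no call in edgeR at any stage, also adjusted over the list alone (adjusted p = 0.25, 0.11, 0.15 and 0.15). As a list they passed, down, at E5 without left 1 or right 3 and at E6.5 without left 3 or right 1. W chromosome genes (6) had 1 call, SPIN1W at E8 (-0.30), also adjusted over the list alone (adjusted p = 0.85, 0.47, 0.58 and 0.78). SPIN1W had adjusted p = 0.14, 0.099, 0.18, 0.18, 0.15 and 0.086 without left 1, 2 and 3 and right 1, 2 and 3. The median, the mean and the test did not share a sign for WNT genes at all 4 stages, for apoptosis genes at E5, E6.5 and E8, for steroid synthesis genes at E8 and E9.5, for surface epithelium and muscle genes at E6.5 and E8, for hedgehog and PDGF, BMP, neural, Müllerian duct and W chromosome genes at E5, for embryonic left-right axis and retinoic acid genes at E6.5 and for testis and Sertoli genes at E9.5. None of these passed there in the main setting.

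A set of 60 genes was higher in the left gonad at all 4 stages, where 0.033 would be shared if the stages were independent, and 20 were lower at all 4 (0.0052). Beside MSTN and GRIA1 they include, as genes chosen after their values were seen, GABRA3, a GABA receptor subunit (log2 0.89, 1.65, 2.71 and 2.20 at E5, E6.5, E8 and E9.5) and EPHB1 (0.56, 0.97, 1.22 and 1.55). From the lists come EMX2 (1.14, 0.85, 1.41 and 1.68), KRT7, BMP3 and the germ cell genes DDX4, TDRD9, RNF17 and DMRTB1. The genes lower at all 4 stages include CPNE8 (-1.89, -1.20, -0.94 and -0.83), C7 (-1.26, -0.82, -1.48 and -1.66), TCF21 (-0.92, -0.73, -0.93 and -1.12) and SLIT2 (-0.51, -0.49, -0.93 and -1.01). E5 and E9.5 shared 77 genes higher on the left (16.4 if independent) and 60 lower (13.4). E8 and E9.5 shared 552 and 547 (64.6 and 88.2). Stages share no libraries, but genes are not independent of each other. The tests at all stages also use the same estimate of spread for a gene. Calls of a gene at different stages are thus not independent, and the expected numbers are a loose reference only.

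**Figure D2:**
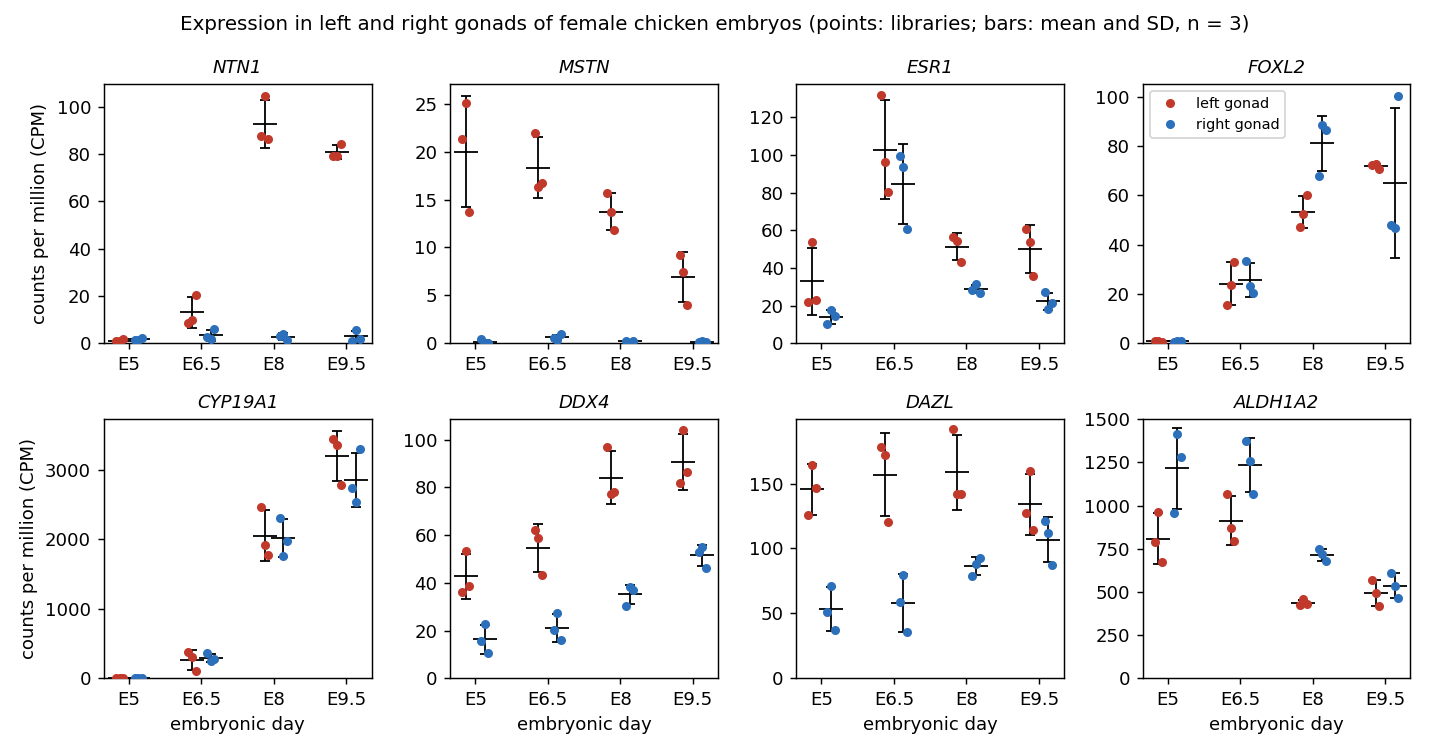
CPM (vertical axis) of NTN1, MSTN, ESR1, FOXL2, CYP19A1, DDX4, DAZL and ALDH1A2 in each left and right library at E5, E6.5, E8 and E9.5, with the mean and SD of 3 libraries. NTN1 stands at 80.9 CPM on the left and 2.86 CPM on the right at E9.5, where CYP19A1 reaches 3195 and 2857 CPM.

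The left-right difference varied over the 4 stages for 342 genes, and between E5 and E9.5 it changed for 368 (145 toward the left and 223 toward the right, 275 by at least 2-fold). NTN1 went from a log2 of -0.57 at E5 to 4.79 at E9.5 (difference 5.36 ± 0.81, adjusted p = 0.0010). SHISA6 (-1.08 to 3.32, adjusted p = 3.0e-05), TGM4 (-0.19 to 3.57), RASD2 (-0.38 to 3.19, 2.6e-07) and the serotonin receptor gene HTR1B (-0.48 to 2.40, 4.8e-07) also moved toward the left. In the other direction PALMD went from 4.07 to -0.15 (difference -4.22 ± 0.43), FAS from 2.49 to -0.09 (-2.57 ± 0.39) and PAX2 from -0.43 to -2.44 (-2.01 ± 0.33). None of the 20 panel genes passed either test. In all, 20 genes were called on opposite sides at the 2 stages, 13 higher on the left at E5 and 7 at E9.5, for example SERPINB10B (3.95 to -1.94). The count of 342 was 217, 196, 221 and 212 without E5 left 2, left 3, right 2 and right 3, 220 without E6.5 right 1, 195 without E9.5 left 2, 182 with the adrenal and chromaffin score as a covariate and 817 with DESeq2. Of the 368, more moved toward the right than the left, but this was not stable, with 157 toward the left and 155 toward the right without E5 right 1, 120 and 128 without E5 left 2, and 148 and 119 with the adrenal and chromaffin covariate. The count of 368 was 245 without E5 right 3, 671 with DESeq2 and 692 with the replicate block, where DAZL (-1.16, adjusted p = 0.018) and NR5A1 (-0.83, adjusted p = 0.032) passed and 1 of 41 named genes lost its call.

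Of the lists, 5 changed between E5 and E9.5, and each lost its call with an estimated correlation. With fry the germ cell (adjusted p = 0.085), mesonephros (0.18), adrenal and chromaffin (0.18) and cell cycle (0.057) lists lost theirs as well. Germ cell genes moved toward the right (5 of 27, none the other way, 12 adjusted over the list alone). For germ cell genes the median was -0.68, with adjusted p = 1.7e-07, and adjusted p = 0.44 with an estimated correlation. Examples are NANOG (-2.46 ± 0.42), LIN28A (-2.12 ± 0.43) and the receptor gene KIT (-1.68 ± 0.34). Mesonephros genes did so too (PAX2 alone of 18, also adjusted over the list alone). For mesonephros genes the median was -2.59, with adjusted p = 2.5e-04, and adjusted p = 0.49 with an estimated correlation. Adrenal and chromaffin genes moved toward the left (MC2R and CHGB of 13, 6 adjusted over the list alone). The adrenal and chromaffin median was 2.64, with adjusted p = 1.9e-04, and adjusted p = 0.49 with an estimated correlation. Cell cycle genes moved toward the left with no gene past the threshold in edgeR (0 of 28, 1 adjusted over the list alone; median 0.27, adjusted p = 4.8e-06, and adjusted p = 0.33 with an estimated correlation), and so did immediate early and heat shock genes (ATF3 alone of 20, also adjusted over the list alone; median 0.24, adjusted p = 0.0044, and adjusted p = 0.33 with an estimated correlation).

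**Figure D3:**
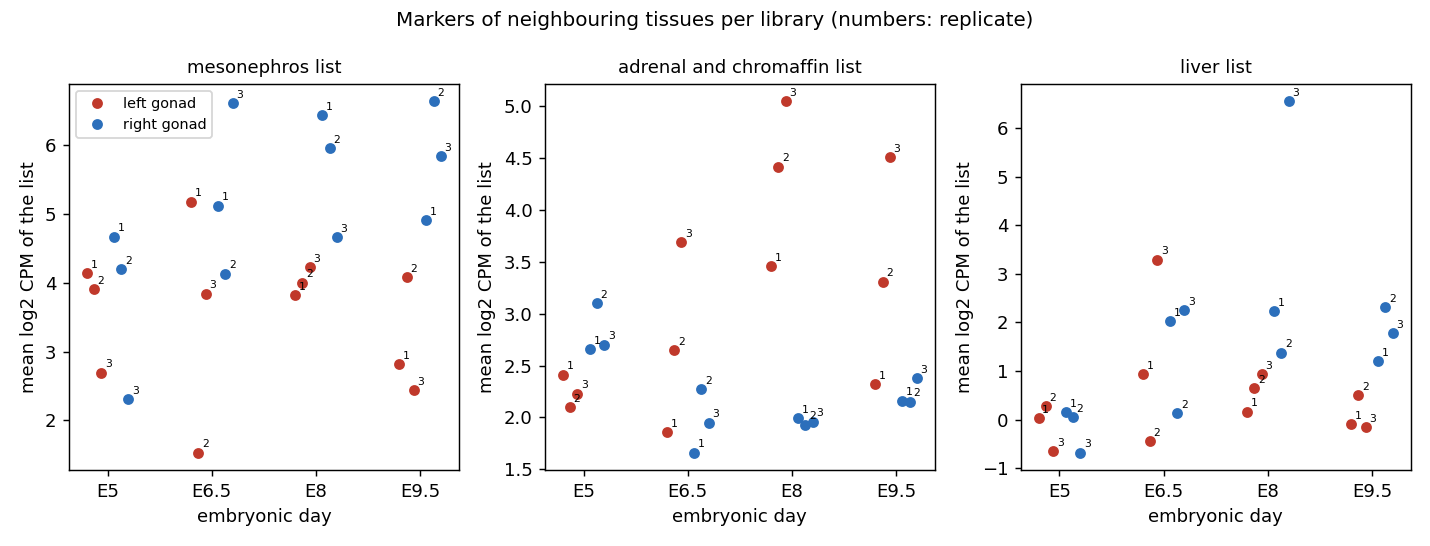
Mean log2 CPM of the mesonephros, the adrenal and chromaffin and the liver list in each of the 24 libraries (vertical axis), by stage and side, with replicate numbers. The liver list stands at 6.55 in E8 right replicate 3 and at 3.29 in E6.5 left replicate 3, against -0.68 to 2.31 in the other 22 libraries.

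From E5 to E9.5 both gonads gained the transcripts of oestrogen synthesis. CYP19A1 rose from 0.959 ± 0.221 to 3195 ± 361 CPM in the left (log2 11.69 ± 0.55, adjusted p = 5.6e-12) and from 0.547 ± 0.526 to 2857 ± 391 CPM in the right gonad (12.33 ± 0.58). CYP17A1 rose by 8.38 ± 0.32 and 8.84 ± 0.33 on the log2 scale, HSD17B1 by 6.61 ± 0.26 and 6.06 ± 0.25, and FOXL2 by 6.46 ± 0.38 and 6.38 ± 0.38. ZP3, a gene of the egg coat, rose by 8.72 ± 0.56 and 8.36 ± 0.53. SOX9 fell by 2.77 on the log2 scale in the left and by 4.30 in the right gonad, and HAND1 by 6.99 and 6.31. The embryonic globin gene HBZ fell by 6.83 and 6.74, while HBBA rose by 6.59 in the left gonad and HBE1 by 6.78 and 7.03.

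In the left gonad 5703 genes changed between E5 and E9.5 (3039 rose, 2664 fell) and in the right gonad 6267 (3583 rose, 2684 fell), with 45.8% and 43.2% of genes without overlap against 10% by chance. The excess of rises was not stable. In the left gonad 2434 genes rose and 2445 fell without E5 left 3, and in the right gonad 2701 rose and 2710 fell without E5 right 1 and 2595 and 2630 without E9.5 right 2. The gonads shared 2200 rises (652 if independent) and 1746 falls (428), and 19 genes rose in the left and fell in the right, with 30 the other way. Changes were correlated across genes (r = 0.64), which are not independent replicates. Both tests also use the same estimate of spread for a gene.

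Ovarian somatic genes rose in both gonads (left 10 and right 9 of 16 up, 2 and 1 down, the same adjusted over the list alone; medians 1.08 and 1.32, adjusted p = 4.7e-04 and 5.7e-04, and adjusted p = 0.032 and 0.046 with an estimated correlation), and so did steroid synthesis genes (10 of 19 in each, none down, 10 and 11 adjusted over the list alone; adjusted p = 6.4e-04 and 6.6e-04, and adjusted p = 0.033 and 0.050 with an estimated correlation, of which the second does not pass). Meiosis genes rose (left 8 up and 1 down, right 6 up of 15, 9 and 1 and 7 adjusted over the list alone; adjusted p = 0.014 and 0.025, and adjusted p = 0.45 and 0.60 with an estimated correlation), with STRA8 up by 2.59 ± 0.37 and 3.63 ± 0.44 and SMC1B by 4.79 ± 0.37 and 4.33 ± 0.38. Germ cell genes rose in the right gonad (20 up and 2 down of 27, 20 and 3 adjusted over the list alone; median 1.28, adjusted p = 5.7e-04, and adjusted p = 0.73 with an estimated correlation), and in the left gonad 14 rose and 7 fell (the same adjusted over the list alone; adjusted p = 0.18). DAZL rose in the right gonad (53.2 ± 17.2 to 107 ± 17.4 CPM, adjusted p = 0.0035) and had a log2 of -0.12 in the left (adjusted p = 0.75), where LIN28A fell by 3.38 and PRDM14 by 1.89. In the left gonad the embryonic left-right axis fell (4 of 7, the same adjusted over the list alone; median -0.99, adjusted p = 0.0080, and adjusted p = 0.033 with an estimated correlation), as did retinoic acid genes (3 up and 9 down of 18, 4 and 10 adjusted over the list alone; median -0.83, adjusted p = 0.0080, and adjusted p = 0.080 with an estimated correlation) and Müllerian duct genes (4 of 8, 5 adjusted over the list alone; adjusted p = 0.032, and adjusted p = 0.34 with an estimated correlation). In the right gonad these 3 lists had adjusted p = 0.23, 0.23 and 0.17. The change itself did not differ between the gonads past the threshold (camera adjusted p = 0.11, 0.092 and 0.45 for the difference of differences).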

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

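The left-right difference at E9.5 minus that at E5 was tested for every named gene and list, and those that passed and are reported here stand as log2 values. Toward the left they were NTN1 5.36, MC2R 4.82, SHISA6 4.41, TGM4 3.77, RASD2 3.57, DRD4 3.41, CHGB 3.25, RGS7 3.09, TOM1L1 2.92, HTR1B 2.87, G0S2 2.69, ATF3 2.07, WNT6 1.65, ADARB2 1.58, OGN 1.33, CPNE8 1.07, LEF1 0.99 and C4H4ORF32 0.97. Toward the right they were ID3 -0.61, PDGFA -0.81, ID2 -0.84, TGFBI -1.18, DHRS3 -1.23, COL14A1 -1.31, WNT11 -1.54, KIT -1.68, DKK1 -1.70, C2orf88 -1.78, PRDM14 -1.90, MGP -1.99, PAX2 -2.01, LIN28A -2.12, NANOG -2.46, FAS -2.57, PDC -2.60, RPH3A -3.09, CAMP -4.09, AvBD2 -4.12, PALMD -4.22, LECT2 -4.25, LYG2 -4.30, S100A9 -4.43, FAM135B -4.57, PI3 -4.65, SERPINB10B -5.89 and TMEM72 -8.06. Runs with a library left out covered the 41 called genes named for this contrast itself. Genes named only for a comparison at a single stage were not rechecked. Some of the 41 lost their call. DRD4 had adjusted p = 0.059 without E5 right 1, G0S2 0.063 without E5 right 2, PRDM14 0.053 without E5 right 3, MGP 0.056 and LYG2 0.073 without E9.5 left 2, ID2 0.059 without E9.5 left 1, ID3 0.086 without E9.5 right 2, OGN 0.11 without E5 right 2, LECT2 0.11 and TGFBI 0.093 without E5 left 3 and LEF1 0.13 without E5 right 3. LYG2 reached 0.078 without E5 right 3. The lists were germ cell (-0.68), cell cycle (0.27), mesonephros (-2.59), adrenal and chromaffin (2.64) and immediate early and heat shock (0.24).

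The 3 patterns below, and their tests, were chosen after the results were seen. The predictions for carried-over tissue and for germ cell number were written before those tests were run, and the tests of scaling and of dilution were written after. In each held-out test the list was divided in 2 parts, and each part was tested with a score from the other as a covariate. Across the 24 libraries, within groups, the parts were correlated for the mesonephros (r = 0.94, p = 1e-05, rho = 0.95, r = 0.93 without the 2 farthest libraries), adrenal and chromaffin (r = 0.85, p = 0.0017, rho = 0.68, r = 0.77) and germ cell lists (r = 0.93, p = 2e-05, rho = 0.92, r = 0.93), in 3 relations with 100000 permutations.

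Mesonephros genes were lower in the left libraries at E8 and E9.5, and carried-over mesonephros tissue could account for this. With the score as a covariate the held-out median was -0.52 at E8 and 0.29 at E9.5 (the part farther from 0), so the prediction was met at E9.5 and stayed open at E8. The list median stayed at -1.995 and -3.06 with RLE factors or thinned libraries, which is only weak evidence against scaling or depth. Totals differed by a ratio of 1.32. At E8 the median over all genes was -0.038, and -0.025 and -0.023 with these settings. They could thus hardly have brought a list median near 0. The held-out test cannot tell carried-over tissue from a difference between the sides in the tissue itself, since the score would remove either. That difference was not tested and remains open.

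Adrenal and chromaffin genes were higher in the left libraries at E8 and E9.5, which carried-over adrenal or chromaffin tissue could explain. The held-out median was 0.66 at E8, where the test left it open, and -0.41 at E9.5, where the prediction was met. The prediction also asked for a minimum correlation between the parts. That was met at r = 0.85, but not at r = 0.77 without the 2 farthest libraries. With RLE factors or thinned libraries the list median stayed at 3.18 and 1.64, again only weak evidence against scaling or depth. Neural genes such as SNAP25 and STMN2 moved with this list at E8, while at E9.5 the neural and glial list had 1 gene higher and 1 lower of 13 and did not pass (adjusted p = 0.78). A difference between the sides in the embryo was not tested, and a score from the same list would remove it too.

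Germ cell genes were higher in the left libraries at E5 and E6.5, and more germ cells in the left gonad could account for it. The held-out median fell to 0.298 at E5, just inside the limit of 0.30 set beforehand, and to 0.15 at E6.5, as that explanation predicts. Dilution of the right libraries by other tissue was tested with 35 gonadal somatic genes, with medians of 0.096 at E5 and -0.0019 at E6.5. At E5 the test cannot decide. The ovarian somatic list was low there (mean log2 CPM from 2.25 to 2.74 per library), and the surface epithelium list was higher on the left (camera adjusted p = 0.0026). At E6.5 the quartiles of the somatic genes, -0.31 and 0.24, argue against dilution, since those of germ cell genes were 0.96 and 1.38. With RLE factors or thinned libraries the germ cell median stayed at 1.25 and 1.22. More transcript per germ cell was not tested, and a score from the same genes would remove it too.

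Libraries were also split in other ways than by side or stage. With 10 splits there are too few for a share under 0.05, and the real split gave the most calls in each case, ranking 1: 490 at E5 (highest other 2), 541 at E6.5 (0), 2379 at E8 (0), 2171 at E9.5 (2), 5703 in the left gonad over time (0) and 6267 in the right (0). For the difference over 4 stages the real split ranked 1 of 100 (342, highest other 162). For E9.5 against E5 it ranked 4 of 100 (368, highest other 1832), and the 3 above it exchange all left and right libraries at E9.5. The one with 1832 leaves E5 as it was, which turns the difference of the side effects into their sum, and those with 463 and 457 also exchange 1 library at E5. Both tests between stages redrew the sides within each stage, which also breaks a side difference common to the stages. Their ranks thus do not tell whether the difference varies with stage.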

How the results depend on the processing

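The counts of calls moved by more than 1.5 times as follows, and the cause was not tested. With the replicate block they were 814 at E5, 862 at E6.5, 3343 at E9.5, 607 over the 4 stages and 692 for E9.5 minus E5. With the compared libraries alone they were 222, 77 and 1032 at E5, E6.5 and E9.5. The mesonephros covariate gave 279 at E6.5 and 760 at E9.5, the adrenal and chromaffin covariate 1484 at E8 and 182 over the 4 stages, and DESeq2 817 and 671 for the 2 tests between stages. With single libraries left out the counts ran from 236 to 413 at E5, 198 to 571 at E6.5, 1349 to 1994 at E8, 1013 to 2332 at E9.5, 195 to 360 over the 4 stages and 245 to 413 for E9.5 minus E5. Lists passing fell from 7 to 3 at E5, 8 to 0 at E6.5, 11 to 0 at E8 and 9 to 0 at E9.5 with an estimated correlation, and to 4 with fry and 5 without E6.5 left 1 at E6.5. Of 7 signs that turned, 6 are reported here, with the adrenal and chromaffin covariate at E8 for PNMT (-0.54), STMN2 (-0.14) and TUBB3 (-0.58), and with the mesonephros covariate at E9.5 for AMN (0.38), AvBD10 (0.18) and TMEM52B (0.28). PNMT and AMN are part of those scores, so their signs are no test. Those scores also parted the sides at these stages, so the other signs cannot tell carried-over tissue from a side difference. Of 11275 values for single genes and lists, 9912 stayed the same, which includes values that were not called in either setting. With single libraries left out, 29 of 57 named genes called at E5 lost their call at least once. At E6.5, E8 and E9.5 these were 23 of 50, 37 of 96 and 41 of 92. Depth of 15078282 to 19970859 counts limits what can be said of genes under 2 CPM.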

Other observations

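The genes in this part were chosen after their values were seen. No family of transmitter receptors was tested as a set. At E8, 3 of 23 glutamate receptor genes were higher and 5 lower in the left gonad, 6 and 1 of 17 GABA-A receptor genes, and 3 and 2 of 25 serotonin, dopamine and adrenergic receptor genes. At E5 these counts were 3 and 1, 1 and 1, and 0 and 2, at E6.5 they were 3 and 0, 3 and 1, and 1 and 0, and at E9.5 they were 2 and 6, 1 and 2, and 4 and 6. With the adrenal and chromaffin covariate 4 GABA-A receptor genes were higher at E8. With the mesonephros covariate the serotonin, dopamine and adrenergic receptor genes lower in the left gonad were 4 at E5, 0 at E6.5, 0 at E8 and 1 at E9.5, and the glutamate receptor genes 1, 0, 5 and 5. Of 19 neuropeptide receptor genes 2, 2, 9 and 7 were higher and 1, 1, 2 and 2 lower at E5, E6.5, E8 and E9.5, with 2 higher at E8 and 5 at E9.5 under the adrenal and chromaffin covariate. GABRA3 was higher in the left gonad, at 144 ± 4.33 against 21.9 ± 4.06 CPM at E8, and HTR1B at 309 ± 39.3 against 58.5 ± 10.99 CPM at E9.5 (log2 2.40). GRIA2 was lower in the left gonad at E8 (-1.36) and E9.5 (-1.37), opposite to GRIA1. EPHB1, a receptor of cell guidance, stood at 158 ± 1.83 against 54.2 ± 8.77 CPM at E9.5. Of 31 HOX genes tested, 1 was lower in the left gonad at E5 (HOXB5), 2 at E6.5 (HOXB2 and HOXB4), 9 at E8 and 12 at E9.5, and 1 was higher at E8 (HOXA7). HOXB4 was at -0.97 at E8 and -1.08 at E9.5. With the mesonephros covariate 8 were lower at E8 and 8 at E9.5.

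The following tests were chosen after the first results were seen, with their predictions written before they were run. Interferon-stimulated genes IRF1 (log2 2.16 at E8, 2.08 at E9.5), MX1 (1.74 and 3.22) and IFIT5 (1.34 and 1.64) were higher in the left gonad. If interferon-stimulated genes were higher as a set, 36 members not yet looked at could be higher too. They did not pass at E8 with camera (adjusted p = 0.30, and adjusted p = 0.28 with an estimated correlation), but did with fry (adjusted p = 0.046). At E9.5 they passed (camera adjusted p = 0.0021, median 0.29, 28 of 36 up). Of 7 granule genes, among them CAMP and S100A9, 4 were higher in the left gonad at E5 and 5 at E6.5, with 0 lower. If heterophils were more numerous in the left libraries, 20 unseen heterophil genes might be higher. They did not pass at E5 (adjusted p = 0.12) and passed at E6.5 (adjusted p = 0.022, and adjusted p = 0.25 with an estimated correlation). The heterophil list and the liver list both hold TF.

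The liver list was written after the data were seen. It had 0 of 24 genes higher and 22 lower in the left gonad at E8, and 0 and 5 at E9.5. ALB stood at only 4.1 to 8.2 CPM in the E9.5 libraries. There the liver score was -0.16 to 0.5 in the left and 1.2 to 2.31 in the right libraries. The mesonephros score was higher on the right too (2.44 to 4.08 and 4.91 to 6.64). Whether the 5 calls reflect liver tissue was not tested. In E8 right replicate 3, 23 of 24 liver genes had their highest value.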
